A study of Mus musculus with 4 samples.

How the data were processed

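Gene expression was measured on mouse Affymetrix arrays in haematopoietic stem cells (HSC) sorted by flow cytometry with a KLS CD48- CD150+ gate. Per the labels, recombination was started in adult mice by tamoxifen injection, the cells were isolated 2 weeks later, and every sample was a pool from 3 mice. Total RNA was extracted with Trizol and made into biotinylated cRNA, per the labels' protocols. There were 2 groups of 2 pools each, Rb family deficient (genotype label Rb -/- p130 -/- p107-/-) and wild type (genotype label Rb +/+ p130 +/+ p107-/-). Groups were taken from the sample titles. The pools of a group carry different numbers, and nothing states whether any mouse entered more than 1 pool. The limma p-values of genes therefore measure the spread between these pools.

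The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (background correction, quantile normalization and probe set summary). RMA and limma are named in the submitters' processing notes, with versions and settings not given in the sources used here. The log2 scale was read from the values, which ran from 2.65 to 14.9 with array medians between 5.93 and 6.01. Because RMA gives every array nearly the same distribution, a change in total RNA per cell would not show in these values. RMA also compresses folds of dim probe sets. Scanner files and detection calls were not used here, so no statement is made on whether a probe set was above background. The number of arrays limits the precision of each value.

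The table held 45101 probe sets, of which 64 were array controls. The platform annotation, of 2016, listed exactly 1 gene symbol for 34945 probe sets and several genes for 932, and 9160 had no listed gene and are unnamed here. Symbols were updated through the Entrez gene ID with a RefSeq gene table of assembly GRCm38.p6, in which 34741 of the 34945 probe sets found their gene. No coordinates are given, since the array values carry no genome build. Each gene was represented by the probe set with the highest mean over the 4 arrays, among those with 1 gene symbol, which gave 18193 genes. No filter on dim probe sets was applied. The other 10092 probe sets were tested separately as probe sets.

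Differences were computed as Rb family deficient minus wild type with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, with no block, Benjamini-Hochberg adjustment over all genes and an adjusted p threshold of 0.05. Every adjusted p of a gene in the text is from this limma fit, and every SE of a gene or probe set is the moderated standard error of the log2 difference. The SE of a median over several genes is instead the spread of that median over 10000 random redraws of those genes. It treats the genes as independent and does not measure the spread between pools. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 24 lists together, 14 gene lists and 10 lists of cell type markers. Camera asks whether a list's genes shift relative to all other genes. At a preset correlation its p-values rest on the spread over genes and do not measure the spread between pools. Each list was also tested with the correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. The position of each list's median among 10000 random lists of the same size, matched on mean expression in 20 bins, was also computed.

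The groups, tests, lists and rule for naming genes were fixed before the data were examined. Named genes are the targeted genes and sort markers (Rb1, Rbl1, Rbl2, Slamf1, Cd48, Kit and Ly6a), up to 12 genes in each direction, up to 4 genes with the smallest p in each list, and E2f1, E2f2, E2f3, Ccne1, Ccne2 and Socs3. The 12 in each direction were to be the genes past the threshold with the largest change and with both deficient arrays on the same side of both wild type arrays, and otherwise those with the smallest p, said not to have passed. Predicted genes, RIKEN clones and expressed sequence symbols were passed over. Members named beyond this rule are said to have been chosen after their values were seen. Ly6a had no probe set with 1 gene symbol and has no value here. Socs3 was put on the lists from knowledge of the study, so its place there is not independent evidence.

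The gene lists were E2F targets and DNA replication, G2/M and mitosis, HSC-associated genes, CDK inhibitors and quiescence, JAK-STAT signalling and SOCS, interferon response, p53 targets, homing and adhesion, Notch pathway, oxidative phosphorylation, glycolysis and hypoxia, cytosolic ribosomal proteins, apoptosis regulators, and immediate early genes. The marker lists were for granulocyte and monocyte progenitors, mature neutrophils, macrophages, erythroid cells, megakaryocytes, B cells, T and NK cells, multipotent and lymphoid progenitors, mast cells and basophils, and endothelial and stromal cells.

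The fit was tested on 20 simulated data sets that used the means and residual spreads of the 18193 genes, with 200 genes changed in each. For this comparison, the adjusted threshold was passed by 3.58% of genes changed 2-fold, 58.7% of genes changed 4-fold and 75.5% of genes changed 8-fold, with 1.6 unchanged genes called per set. Camera called a list of HSC-associated genes lowered by 0.3 in 20 of 20 simulated sets and called 0.15 other lists per set when none was shifted. These simulations drew genes independently of each other. The 200 changed genes of a set mixed 2-fold, 4-fold and 8-fold changes. With fewer changed genes the adjusted threshold is harder to pass, so the shares can overstate the power in the real data.

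Alternatives were the replicate number as a block, quantile normalization again, median centring, only genes above the median expression, the mean of a gene's probe sets, probe sets with _x_at or _s_at names left out where a gene had another, eBayes with trend and robust fitting, each array left out in turn, probe sets in place of genes, other thresholds, and the estimated correlation and fry for the lists. Crossed replicate pairs as a block, counts at an unadjusted p under 0.05, and left-out arrays for Klf4, Egr1, Ctnnal1, Hspa1a, Hspa1b and 14 heat shock genes were added after seeing the data.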

Results

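HSC with acute loss of the retinoblastoma family were compared with wild type HSC to see which genes differ 2 weeks after recombination. The retinoblastoma family comprises Rb1, Rbl1 (p107) and Rbl2 (p130), which restrain E2F transcription factors and entry into the cell cycle. The data were 4 arrays, 2 from Rb family deficient pools and 2 from wild type pools, each pool from 3 mice. The genotype labels give p107 as -/- in both groups, so the groups differ by label in Rb1 and Rbl2. Array medians were 6.01 and 5.98 in the deficient pools and 5.93 and 5.96 in the wild type pools on the log2 scale. Over all genes, the deficient pools correlated with each other at a Pearson's r of 0.990 and the wild type pools at 0.987, and pairs across the groups ran from 0.983 to 0.990. These correlations are across genes, which are not independent replicates. Y-linked genes were lower in both deficient pools, with Eif2s3y at 8.50 and 9.64 against 9.93 and 10.29 and Kdm5d at 6.12 and 7.86 against 8.26 and 8.37 in the wild type pools. The 3' minus 5' difference of the Actb control probe sets, a sign of RNA quality, was 3.13 and 2.95 against 2.32 and 2.81, while that of Gapdh, at 2.79 in deficient pool 1 and 2.40 to 2.58 in the other pools, did not separate the groups.

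Of the targeted genes, Rbl2 had log2 values of 7.82 and 8.21 in the deficient pools and 8.94 and 8.75 in the wild type pools, 1.78-fold lower (log2 difference -0.83, SE 0.19, n = 2 pools per group, limma adjusted p = 0.761). The second Rbl2 probe set differed by -0.33 (SE 0.17). Rb1 stood at 9.82 and 9.72 in the deficient pools against 9.37 and 9.58 in the wild type pools, a difference of 0.29 (SE 0.16), and its second probe set differed by 0.46 (SE 0.25). The Rbl1 probe set with the highest signal stood at 5.35 and 5.42 against 5.92 and 6.77, a difference of -0.96 (SE 0.30, limma adjusted p = 0.761). The 3 others were dimmer and differed by 0.03, 0.03 and -0.000873. The positions of these probe sets relative to the deleted parts of the genes are not given in the sources used here, so the values do not check the labels. The sort marker Slamf1 (CD150) differed by 0.24 (SE 0.40), Cd48 by -0.03 (SE 0.42) and the stem cell factor receptor Kit by -0.59 (SE 0.28). Slamf1 turned below 0 without deficient pool 2 (-0.08) or wild type pool 1 (-0.28), and Cd48 above 0 without deficient pool 1 (0.11) or wild type pool 2 (0.59). Kit differed by -0.34 without deficient pool 1, -0.28 without wild type pool 1, -0.90 without wild type pool 2 and -0.03 with the mean of its probe sets, Rb1 by 0.19 without wild type pool 1 and Rbl1 by -0.53 without wild type pool 2.

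The gene with the lowest p was Socs3, a feedback inhibitor of cytokine receptor signalling. Its log2 values were 10.91 and 11.14 in the deficient pools and 8.56 and 8.71 in the wild type pools, 5.23-fold higher (log2 difference 2.39, SE 0.16, n = 2 pools per group, limma adjusted p = 0.326). Both other Socs3 probe sets were also higher, by 2.17 (SE 0.16) and 0.83 (SE 0.16). The larger values are from probe sets with _x_at names, which can hybridise to other transcripts. The dimmer probe set at 0.83 is the only one without such a name, so Socs3 differed by 0.83 with specific probe sets first. With the mean of its probe sets it differed by 1.80. Ptgs2, the inducible cyclooxygenase, was 4.45-fold higher (log2 2.15, SE 0.20) and the neutrophil chemokine Cxcl2 4.52-fold higher (log2 2.18, SE 0.23). The stefin genes Stfa3 and Stfa2l1 were higher by 2.70 (SE 0.22) and 3.08 (SE 0.32) on the log2 scale. The stefin A genes are close paralogs, and a probe set for one can hybridise to transcripts of another. The decoy interleukin-1 receptor Il1r2 differed by 1.38 (SE 0.17) and Lrg1 by 1.27 (SE 0.15). The transcriptional regulators Skil (1.30, SE 0.17), Klf2 (1.18, SE 0.16), Id2 (1.98, SE 0.31) and Klf5 (1.02, SE 0.16) and the kinase gene Sgk1 (1.16, SE 0.17) made up the 12 genes with the lowest p among those higher. Second, dimmer probe sets gave smaller differences for Ptgs2 (0.52, SE 0.16), Id2 (0.72, SE 0.25), Klf5 (0.66, SE 0.20) and Skil (0.39, SE 0.19), and the dimmest probe sets differed by -0.07 for Id2 and 0.02 for Klf5. With the mean of a gene's probe sets Ptgs2 differed by 1.34, Id2 by 0.88, Skil by 0.84 and Klf5 by 0.57.

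No gene passed the adjusted threshold in either direction. Limma called 0 of 18193 genes higher and 0 lower, while 399 were higher and 735 lower at an unadjusted p under 0.05, 1134 in all against 909.65 that chance gives, and no other gene-level tool was run. The adjusted p was 0.408 for Stfa3, 0.534 for Ptgs2, 0.577 for Stfa2l1 and Cxcl2, and 0.761 for the rest of the 12. At least 2-fold differences were seen for 96 genes higher and 50 lower in the deficient pools. Both deficient arrays lay on one side of both wild type arrays for 6455 genes, or 35.5%, where chance gives 33.3%. With median centring the unadjusted split was 298 higher and 1009 lower. The unadjusted counts moved by over 1.5 times without deficient pool 1, to 244 higher and 317 lower, and the higher count was 689 without wild type pool 2.

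**Figure D1:**
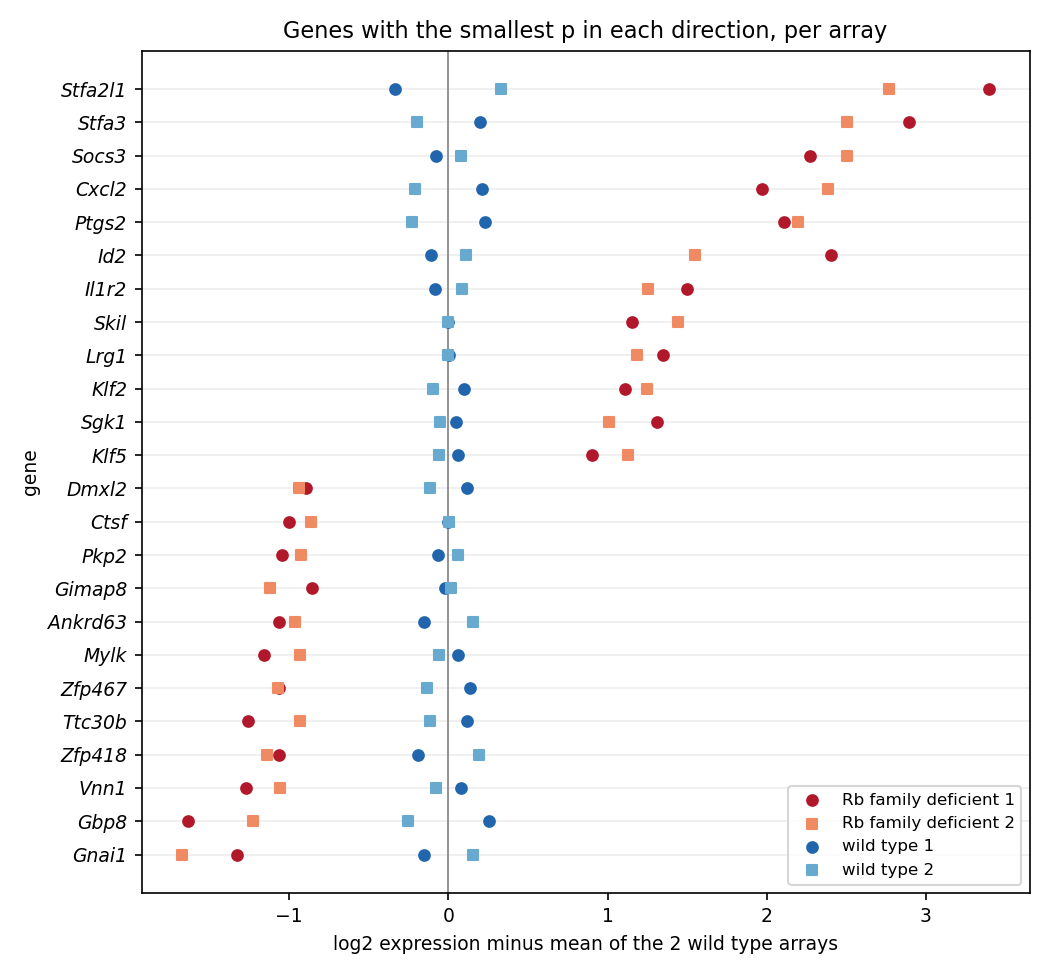
Log2 expression of the 12 genes with the smallest p in each direction, per array, as the difference from the mean of the wild type arrays (horizontal axis), with genes on the vertical axis and no error bars because each point is 1 array. In Socs3 the deficient arrays, at 10.91 and 11.14 before subtraction, lie apart from the wild type arrays at 8.56 and 8.71, and none of the 24 genes passed the adjusted threshold.

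Among the genes with lower values, Gnai1, an inhibitory G protein subunit, was 2.83-fold lower (log2 difference -1.50, SE 0.20, n = 2 pools per group, limma adjusted p = 0.761). Vnn1, which encodes the pantetheinase vanin-1, was 2.24-fold lower (log2 -1.16, SE 0.16), and its second probe set was lower by a similar amount (-1.03, SE 0.18). The guanylate binding protein gene Gbp8 differed by -1.43 (SE 0.24) and the GTPase of immunity associated protein gene Gimap8 by -0.99 (SE 0.16). The zinc finger genes Zfp467 (-1.07, SE 0.16) and Zfp418 (-1.10, SE 0.18) were also among the 12, with Mylk, Ctsf, Ankrd63, Ttc30b, Dmxl2 and Pkp2 at differences between -1.10 and -0.92. The adjusted p was 0.761 for each of the 12. Gnai1 and Pkp2 depended on the probe set, with differences of 0.03 and 0.31 when probe sets specific to the gene came first. The dimmest Gnai1 probe set, also without an _x_at or _s_at name, differed by -0.67 (SE 0.31). A second, dimmer probe set of Ctsf, with an _x_at name, differed by 0.29 (SE 0.15). With the mean of a gene's probe sets Gnai1 differed by -0.71, Mylk by -0.61, Ctsf by -0.32 and Pkp2 by -0.14.

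Genes of DNA replication and mitosis lay above 0 as groups. Of the 66 measured E2F targets and DNA replication genes, 51 were above 0, with a median log2 difference of 0.18. Of the 54 G2/M and mitosis genes, 51 were above 0, with a median of 0.29. Camera passed both, at an adjusted p = 4.28e-07 for the E2F list and an adjusted p = 1.24e-10 for the G2/M list, and each lost its call at an adjusted p = 0.685 with an estimated correlation. The members with the lowest p were E2f2 (1.17, SE 0.27), Orc1 of the origin recognition complex (0.67, SE 0.15), Brca2 (0.56, SE 0.15) and the licensing factor Cdt1 (0.46, SE 0.14) in the first list. In the second they were the phosphatase gene Cdc25c (1.01, SE 0.19), cyclin A2 (Ccna2, 0.69, SE 0.14), Cdca8 (0.55, SE 0.14) and Cdca5 (0.64, SE 0.20). By limma 0 members of either list passed over all genes or adjusted over the list alone, with 9 and 10 members, all higher, at an unadjusted p under 0.05. E2f1 (0.20, SE 0.22), E2f3 (-0.40, SE 0.18), Ccne1 (0.30, SE 0.24) and Ccne2 (-0.18, SE 0.26) showed differences of both signs, and with a pool left out E2f1 ran from -0.000786 to 0.39, E2f3 from -0.58 to -0.21, Ccne1 from 0.07 to 0.53, Ccne2 from -0.47 to 0.10 and Cdca5 from 0.42 to 0.87. The wild type pools differed from each other in the G2/M genes by a median of -0.63, pool 2 the lower. Without wild type pool 2 the adjusted p was 0.185 for the E2F list (median 0.08) and 0.768 for the G2/M list (median -0.03), and without wild type pool 1 the medians were 0.27 and 0.62. With probe sets specific to the gene first, the E2F list had a median of 0.10 (adjusted p = 7.92e-04), and with the mean of a gene's probe sets Orc1 differed by 0.44, Cdt1 by 0.22, Ccna2 by 0.46, Cdca5 by 0.39, Ccne1 by 0.15 and E2f3 by -0.05.

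CDK inhibitors and quiescence genes had a median of 0.09 over 23 members, 14 above 0. Camera gave an adjusted p = 0.00113, and the call was lost at an adjusted p = 0.685 with an estimated correlation. By limma 0 members passed over all genes, 8 were at an unadjusted p under 0.05 and 6 passed adjusted over the list alone. These 6 were the cell cycle inhibitors Cdkn1a (2.25-fold higher, log2 1.17, SE 0.25) and Cdkn2d (1.61-fold higher, log2 0.69, SE 0.16) and the transcription factors Klf2 (1.18, SE 0.16), Hes1 (0.74, SE 0.15), Klf4 (1.92, SE 0.44) and Egr1 (1.66, SE 0.43), the last 2 named after their values were seen. Egr1 is also an immediate early gene on the list of that name. The full list's median was 0.25 without deficient pool 1, 0.24 without deficient pool 2, 0.14 without wild type pool 1, 0.03 with median centring and 0.15 with the mean of a gene's probe sets, and Egr1 differed by 1.00 without wild type pool 1.

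HSC-associated genes lay below 0 as a group, 32 of 44 members with a median of -0.27, or 1.21-fold lower. Between deficient pool 2 and wild type pool 1 the median was -0.08, and the deficient pools differed from each other by 0.19, pool 2 the higher. Camera gave an adjusted p = 2.99e-05, and the call was lost at an adjusted p = 0.685 with an estimated correlation. The members with the lowest p were Procr, the endothelial protein C receptor used as a stem cell marker (1.80-fold lower, log2 -0.85, SE 0.17), the cation channel gene Trpc6 (-0.95, SE 0.21), lymphotoxin beta (Ltb, -0.65, SE 0.15) and Mecom, a transcription factor needed for HSC maintenance (1.62-fold lower, log2 -0.69, SE 0.16). By limma 0 members passed over all genes or adjusted over the list alone, where these 4 had an adjusted p of 0.054, and 13 were lower and 1 higher at an unadjusted p under 0.05. Ctnnal1, named after its value was seen, went the other way at 0.75 (SE 0.24), or 0.44 without deficient pool 2. With the mean of a gene's probe sets Mecom differed by -0.32 and Ctnnal1 by 0.37. The median was -0.15 without deficient pool 1, -0.42 without deficient pool 2 and -0.15 without wild type pool 2, and camera passed the list in each case.

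Glycolysis and hypoxia genes were lower as a group, 23 of 27 below 0 with a median of -0.26. Camera gave an adjusted p = 9.70e-04, and the call was lost at an adjusted p = 0.685 with an estimated correlation. The prolyl hydroxylase gene P4ha1 (-0.48, SE 0.14), Aldoc (-0.71, SE 0.23), the hexokinase gene Hk2 (-0.39, SE 0.15) and Pfkm (-0.55, SE 0.22) had the lowest p, with 0 members past limma's threshold over all genes or adjusted over the list alone and 3 at an unadjusted p under 0.05. The call was lost without wild type pool 1 (adjusted p = 0.101, median -0.12) and without deficient pool 1 (adjusted p = 0.0893, median -0.14), where Pfkm differed by -0.30. With the mean of a gene's probe sets P4ha1 differed by -0.27 and Aldoc by -0.32.

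Immediate early genes, transcribed within minutes of a stimulus, were higher as a group, 21 of 24 above 0 with a median of 0.76, or 1.69-fold. Camera gave an adjusted p = 1.24e-10, and the call was lost at an adjusted p = 0.685 with an estimated correlation. By limma 0 members passed over all genes, 11 were higher and 2 lower at an unadjusted p under 0.05, and 10 passed adjusted over the list alone. Egr2 was 7.88-fold higher (log2 2.98, SE 0.55), Fos 2.15-fold (1.10, SE 0.23), Jund 2.07-fold (1.05, SE 0.21) and Ier3 2.03-fold (1.02, SE 0.22). The heat shock genes Hspa1a and Hspa1b, close paralogs named after their values were seen, lay on the opposite side at -2.33 (SE 0.92) and -1.69 (SE 0.64). Pools of 1 group also differed, with a median of 0.47 between the deficient pools and 0.40 between the wild type pools, pool 2 the higher in both. The median of the list was 0.50 without deficient pool 2. Egr2 differed by 3.84 without deficient pool 1 and 2.11 without deficient pool 2, and Hspa1a and Hspa1b by -0.91 and -0.76 without deficient pool 1, while Jund differed by 0.63 with the mean of its probe sets.

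JAK-STAT signalling and SOCS genes did not shift together (median -0.10 over 39 members, camera adjusted p = 0.516). No member passed over all genes, and 3 passed adjusted over the list alone: Socs3, whose place on the list is not independent evidence, the shared cytokine receptor subunit gene Csf2rb (1.99-fold higher, log2 0.99, SE 0.18) and cyclin D1 (Ccnd1, 3.25-fold lower, log2 -1.70, SE 0.33). With the mean of a gene's probe sets Csf2rb differed by 0.63 and Ccnd1 by -1.07, and the list's median was -0.01 without wild type pool 1. Interferon response genes had a median of -0.14 over 36 members (camera adjusted p = 0.086), with Gbp6 at -2.06 (SE 0.41), Gbp2 at -0.69 (SE 0.23), Oasl2 at -0.70 (SE 0.24) and Irf1 at -0.64 (SE 0.24), the last 3 at -0.44, -0.41 and -0.34 without wild type pool 1. The interferon list passed camera without deficient pool 1 (median -0.23, adjusted p = 0.000165) and without wild type pool 2 (-0.25, 0.000229), and its median was 0.00496 without deficient pool 2 and 0.01 without wild type pool 1. Notch pathway genes had a median of 0.07 (camera adjusted p = 0.169), with Hes1 at 0.74, and a median of -0.03 without deficient pool 1, 0.14 without deficient pool 2 and 0.04 without wild type pool 1. Of the p53 targets (median -0.04, adjusted p = 0.854), Cdkn1a differed by 1.17 and Ddb2 by 0.36 (SE 0.14), and Ddb2 turned to -0.29 when specific probe sets came first and was 0.03 with the mean of its probe sets. Homing and adhesion genes had a median of 0.01 (adjusted p = 0.830), with the chemokine receptor gene Cxcr4 at 0.67 (SE 0.21), or 0.43 without deficient pool 1. Apoptosis regulators (median -0.02, adjusted p = 0.790), cytosolic ribosomal proteins (-0.02, 0.790) and oxidative phosphorylation genes (0.02, 0.830) also did not pass. The oxidative phosphorylation list passed in opposite directions without wild type pool 1 (median -0.15, adjusted p = 0.000870) and without wild type pool 2 (0.20, 0.000472). Single pools also turned medians near 0, to 0.03 for p53 targets and 0.06 for apoptosis regulators without deficient pool 1, to -0.02 there for homing and for oxidative phosphorylation genes, to 0.03 for p53 targets without wild type pool 1, and to 0.02 for ribosomal proteins without wild type pool 2. Of these 8 lists limma called 0 members over all genes and, JAK-STAT genes apart, 0 adjusted over the list alone, with between 0 and 4 members of each list at an unadjusted p under 0.05.

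**Figure D2:**
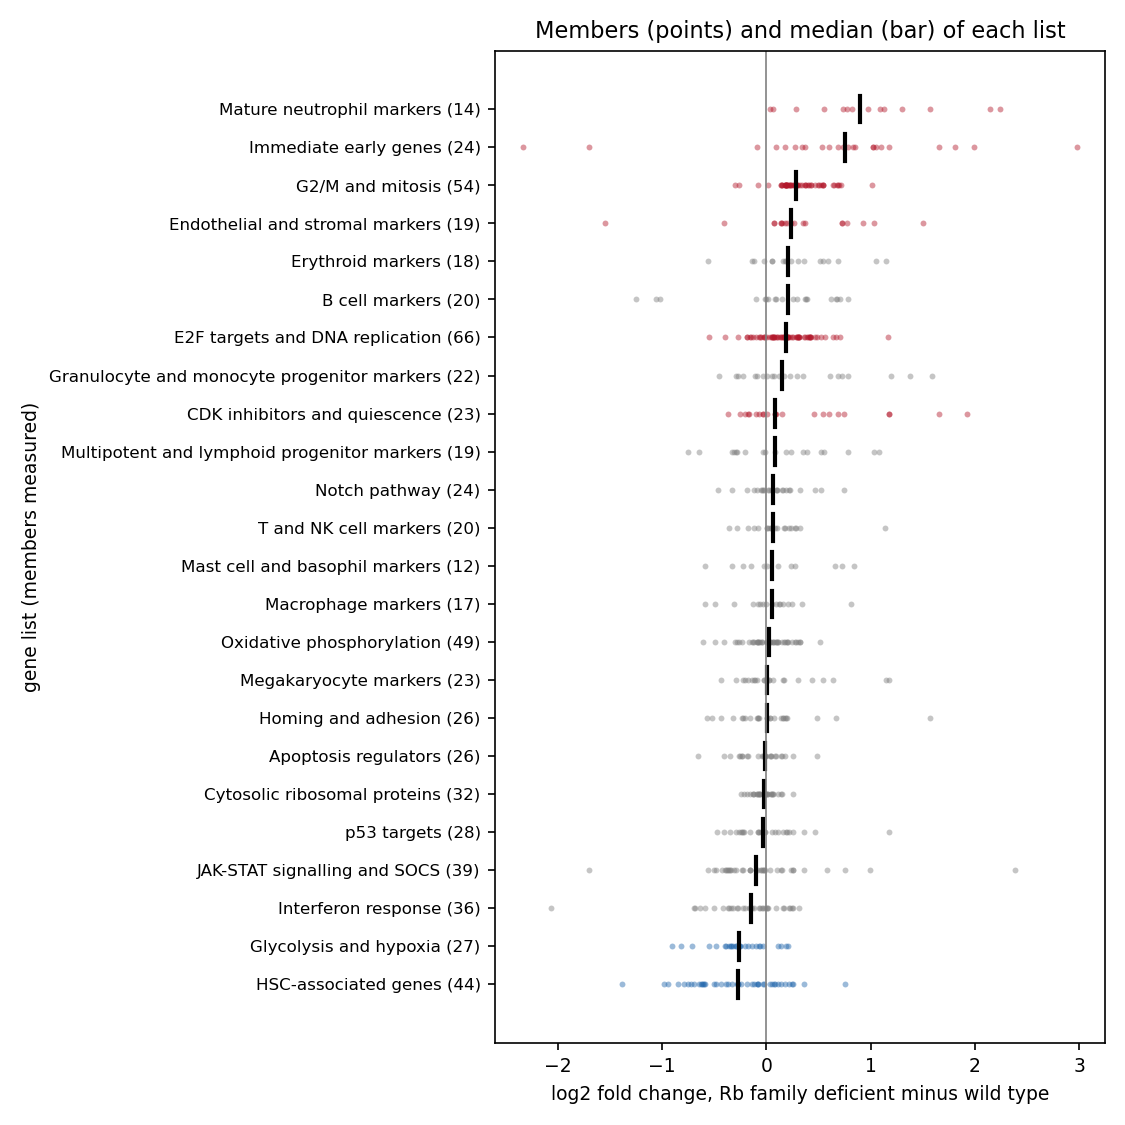
Log2 fold change, Rb family deficient minus wild type, of every measured member of each list (points) with the list's median (black bar), with lists on the vertical axis and their number of measured members in brackets. Red lists were higher and blue lists lower by camera with the preset correlation, and grey lists did not pass. The medians run from -0.27 for HSC-associated genes to 0.90 for mature neutrophil markers.

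Markers of mature neutrophils, a cell type outside the sorted population, were higher as a group, 14 of 14 above 0 with a median of 0.90, or 1.87-fold. Camera gave an adjusted p = 1.57e-08, and the call was lost at an adjusted p = 0.685 with an estimated correlation. Cd177 differed by 0.77 (SE 0.18), Ifitm6 by 2.15 (SE 0.53), the collagenase gene Mmp8 by 2.24 (SE 0.60) and Chil3 by 1.09 (SE 0.36), with 0 members past limma's threshold over all genes or adjusted over the list alone and 6 at an unadjusted p under 0.05. The deficient pools differed from each other by a median of 0.70, pool 1 the higher, and the wild type pools by 0.61, pool 2 the higher. The list's median was 0.40 without wild type pool 1 and 1.53 without wild type pool 2. Mmp8 differed by 1.31 and Chil3 by 0.72 without deficient pool 1, and Chil3 by 0.69 without wild type pool 1.

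Endothelial and stromal markers had a median of 0.23 over 19 members (camera adjusted p = 0.0129), lost at an adjusted p = 0.685 with an estimated correlation. Pdgfrb differed by 1.03 (SE 0.22) and Tie1 by -1.54 (SE 0.53), or -0.79 without wild type pool 1 (Pdgfrb 0.67 with the mean of its probe sets), and the call was lost without deficient pool 1 (adjusted p = 0.778, median -0.10) and without wild type pool 1 (adjusted p = 0.277, median 0.14). The median was 0.51 without deficient pool 2, 0.65 without wild type pool 2 and 0.90 over the 4 members above the median expression (adjusted p = 8.00e-04). The other marker lists did not pass camera with all 4 arrays. Erythroid markers had a median of 0.21 (adjusted p = 0.068), B cell markers 0.20 (0.092), T and NK cell markers 0.06 (0.086), granulocyte and monocyte progenitor markers 0.15 (0.251), megakaryocyte markers 0.01 (0.289), mast cell and basophil markers 0.06 (0.339), macrophage markers 0.05 (0.790) and multipotent and lymphoid progenitor markers 0.08 (0.830). Single pools moved several of these values. Without deficient pool 2 the median was 0.07 for granulocyte and monocyte progenitor, 0.11 for T and NK cell and 0.02 for multipotent and lymphoid progenitor markers. Without wild type pool 2 camera passed erythroid markers (median 0.70, adjusted p = 8.52e-06), granulocyte and monocyte progenitor markers (0.60, 2.21e-05), B cell markers (0.45, 0.0121) and T and NK cell markers (0.20, 0.0141). Without deficient pool 2 it passed erythroid (0.53, 0.0136) and B cell markers (0.36, 0.00142), and without deficient pool 1 granulocyte and monocyte progenitor (0.22, 0.0284) and megakaryocyte markers (0.08, 0.0198). Without wild type pool 1 the medians were -0.28 for erythroid, -0.24 for granulocyte and monocyte progenitor and -0.07 for B cell markers, and without deficient pool 1 they were 0.04 for erythroid and -0.03 for B cell markers. Mast cell and basophil markers had a median of 0.25 without deficient pool 1 and 0.28 without wild type pool 2, macrophage markers -0.08 without wild type pool 1 and 0.21 without wild type pool 2, and multipotent and lymphoid progenitor markers -0.11 without wild type pool 1 and -0.03 without deficient pool 1, while megakaryocyte markers turned to -0.03 without wild type pool 2. Over these 9 lists with the endothelial one, limma called 0 members over all genes, with 0 to 2 of each list at an unadjusted p under 0.05, and 1 passed adjusted over the list alone, the platelet glycoprotein gene Gp1bb (2.26-fold higher, log2 1.17, SE 0.19). Between the wild type pools, erythroid markers differed by a median of 0.92 and granulocyte and monocyte progenitor markers by 0.78, pool 2 the higher.

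**Figure D3:**
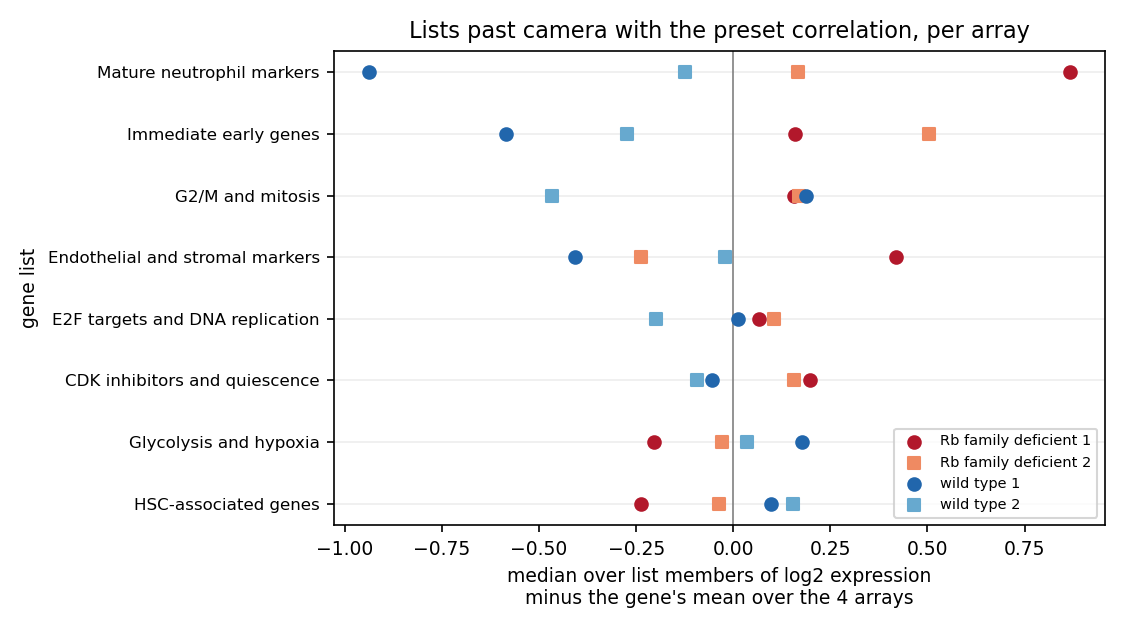
Median over the members of each list of log2 expression minus the gene's mean over the 4 arrays (horizontal axis), for the 8 lists that passed camera with the preset correlation (vertical axis), with 1 point per array. In G2/M and mitosis genes wild type 2 lies at -0.47 while wild type 1, at 0.19, lies beside the deficient arrays at 0.16 and 0.17.

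Of the 24 lists, 8 passed camera with the preset correlation, 6 higher and 2 lower in the deficient pools. With an estimated correlation 0 passed (lowest adjusted p = 0.685), and with fry 0 passed (lowest adjusted p = 0.833). The power of these alternatives with 2 pools per group was not simulated, so the lost calls do not show that no list shifted.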

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

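The counts at an unadjusted p, the crossed pairs and the left-out arrays for Klf4, Egr1, Ctnnal1, Hspa1a, Hspa1b and the 14 heat shock genes were chosen after seeing the data, and the other alternatives before. In every setting limma called 0 genes higher and 0 lower at the adjusted threshold, with the lowest adjusted p at 0.073 with genes above the median expression. At an unadjusted p under 0.05, 399 genes were higher and 735 lower. The higher count was 176 with genes above the median expression and 1530 with probe sets in place of genes, the lower count 408 and 1513, where fewer or more features were tested. Leaving out each array in turn, with the lone array of a group assumed to vary like the other group, gave 244 to 689 higher and 317 to 1082 lower. With the replicate number as a block the lower count was 457. The labels do not say that the numbers pair the pools, and same-numbered arrays deviated from their group means with a correlation of -0.19 across genes. The crossed pairing as a block called 0 genes higher and 0 lower. Of the 24 genes named for the lowest p, 12 in each direction, 12 had no value with genes above the median expression. In the other 10 settings the 24 kept their sign, except Gnai1 and Pkp2 with specific probe sets first, but the differences of 8 changed by over 1.5 times with the mean of a gene's probe sets and those of 3 with specific probe sets first. Of all 123 named genes, 29 to 45 moved by over their SE or across 0 with 1 array left out, 2 to 6 of them across 0, 42 with the mean of probe sets and 9 with specific probe sets first. The 8 lists that passed camera lost their calls at 0.685 with an estimated correlation, and with fry at 0.978 (E2F, G2/M and endothelial lists), 0.833 (HSC-associated, CDK inhibitor, glycolysis and immediate early lists) and 0.912 (neutrophil markers). With each array left out, adjusted p-values ran from 1.11e-13 to 0.185 for the E2F list, 1.09e-36 to 0.768 for the G2/M list, 0.000131 to 0.101 for the glycolysis list and 1.01e-06 to 0.778 for the endothelial list, which turned below 0 without deficient pool 1. Oxidative phosphorylation ran from 0.000472 to 0.736, with 0.000870 in the opposite direction without wild type pool 1. The HSC-associated, CDK inhibitor, immediate early and neutrophil lists passed camera with the preset correlation in every other setting. Neither the replicate number as a block nor any scaling ended the call of any of the 8 lists. The lists were not tested with the crossed pairs. With the replicate number as a block 11 lists passed, which added the interferon response and erythroid lists (both 0.035) and the granulocyte and monocyte progenitor list (0.039). The erythroid list also passed with quantile normalization (0.048), median centring (0.019), genes above the median expression (0.00864) and specific probe sets (0.045). B cell markers passed with median centring (0.038) and specific probe sets (0.046), T and NK cell markers with specific probe sets (0.046), megakaryocyte markers with genes above the median expression (0.00430) and the Notch list with the mean of probe sets (0.042). Over all settings with the preset correlation, left-out arrays included, 7 to 12 lists passed. Apart from the settings that test fewer or more features, the cause was not tested. No scaling moved the median of all genes by over 0.1. Signal over background was not examined here and limits what dim probe sets can show.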

Other observations

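The tests of progenitors and of other splits were chosen after the results were seen. The test of heat shock genes was chosen after the immediate early genes, Hspa1a and Hspa1b were seen and before the values of its 14 genes were. The test of neutrophils was chosen after the 7 genes it concerns were seen and before the values of the markers were, and that of the expression trend after the list's median and before its place among random lists.

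Some differences between the pools followed the groups and others did not. The Y-linked gene Uty, like Eif2s3y and Kdm5d, was lower in both deficient pools, at 5.11 and 6.48 against 6.90 and 6.68, while Xist, transcribed from the inactive X chromosome, lay between 12.72 and 13.28 in all 4 arrays. The granule protease gene Ctsg of granulocyte progenitors, named after its values were seen, stood at 9.43 and 11.80 in the deficient pools and 6.45 and 11.62 in the wild type pools. The first principal component held 48.6% of the variance, with wild type pool 1 at 33.9, deficient pool 1 at -27.8, and deficient pool 2 (-3.25) and wild type pool 2 (-2.92) side by side between them.

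Socs3, Ptgs2, Cxcl2, Stfa3, Stfa2l1, Il1r2 and Lrg1 were higher in both deficient pools, and mature neutrophils, which the KLS gate is meant to leave out, are a candidate source. The abundant neutrophil genes S100a8, S100a9, Camp, Ngp, Ltf and Lcn2 had a median difference of 0.90 (SE 0.14), below the smallest difference of the 7 genes, 1.27. But 3 of the 6 were higher in both deficient arrays than in both wild type arrays, which leaves the explanation open. The sizes cannot decide either, since the starting levels differed. The lowest wild type mean of the 6 was 10.12, while those of the 7 genes ran from 4.31 for Ptgs2 to 8.63 for Socs3. The same added cells need not raise both sets by equal log2 amounts. With specific probe sets first Socs3 differed by 0.83, which is below that median. Between deficient pool 2 and wild type pool 2 the 14 markers had a median of 0.14 and the 7 genes a median of 2.43 and a lowest value of 1.17, while between deficient pool 1 and wild type pool 1 both medians were 1.88. Each of these comparisons rests on 2 arrays and excludes nothing. Effects of the genotype, of the sex of the mice and of RNA quality, where the Actb control probe sets separated the groups, also stay open for the 7 genes. None of the 7 passed the adjusted threshold.

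The immediate early genes were higher in both deficient pools, and stress during handling and sorting is a candidate cause. If it raised heat shock and immediate early genes together, 14 other heat shock genes, among them Hspa8, Hsph1, Dnajb1, Hspd1 and Hspe1, would be higher too. They had a median of -0.40 (SE 0.12, over genes and not pools) with 2 of 14 above 0, which goes against that prediction. Hspa1a and Hspa1b had been seen to be lower before this test was chosen, and each group had 2 pools, so this cause is not excluded. The median of the 14 genes was -0.15 without deficient pool 2. Handling that raises immediate early genes without heat shock genes stays open, as do effects of the genotype, of the sex of the mice and of RNA quality. The immediate early list differed within groups by 0.47 and 0.40 against a median of 0.76 between groups.

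The HSC-associated genes were lower in the deficient pools. A trend of fold change with expression is argued against, since 0% of 10000 random lists matched on expression had a median as low as -0.27. More granulocyte and monocyte progenitors in the deficient pools, cells that the KLS CD48- gate is meant to leave out, may lower the list. This cannot be told apart from an effect of the genotype, of the sex of the mice or of RNA quality here. Against wild type pool 2 the 22 progenitor markers had a median of -0.24 (SE 0.13) while the HSC-associated genes had -0.30 (SE 0.08), but against wild type pool 1 the medians were 0.60 (SE 0.27) and -0.15 (SE 0.10).

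The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. The split by group gave 1134 genes at an unadjusted p under 0.05, and 1 of the 3 splits, the real one, gave as many, with 1121 in the highest of the others. Camera passed 8 lists for the real split, 8 for the split that pairs deficient pool 1 with wild type pool 2, and 10 for the split by replicate number. The E2F and G2/M lists passed in every split. The HSC-associated and immediate early lists also passed by replicate number, and the glycolysis, neutrophil and endothelial lists in the crossed split. Of the lists that passed for the real split, only the CDK inhibitor list passed in no other. Of 10092 probe sets without a single gene, limma called 0 at the adjusted threshold and 720 were at an unadjusted p under 0.05.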
